A study of Homo sapiens with 9 samples.

How the data were processed

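The assay was CUT&Tag, in which an antibody directs a transposase to cut and tag DNA next to the bound protein. An antibody against STAT3, the transcription factor activated by the LIF and IL-6 family of receptors, was used on Mia PaCa2 cells (the pancreatic cancer line also written MIA PaCa-2). Of the 9 samples described, 3 are untreated cells (NC below), 3 are cells over-expressing the LIF receptor LIFR (OE below), and 3 are input DNA of the untreated cells. Groups and replicate numbers were taken from the labels, which do not say whether the untreated cells carried an empty vector. The 3 input samples enter no comparison and are not analysed here. The labels do not say whether replicates were separate cultures, so p-values of the permutation tests measure only the spread between these samples, which may be technical. Fisher's exact tests count genes or regions as independent units. Their p-values do not measure the spread between samples.

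The submitters' processing notes name Bowtie2, SAMtools, MACS2 and deepTools and the build GRCh38, with no versions. Each of the 6 analysed samples has a list of peaks, and peaks were called per sample. Each deposited peak has a fold, the authors' ratio of pileup over local background. The authors also gave each peak a p-value and a q-value as −log10, and an integer score within 1 of 10 times the −log10 q-value. A deposited offset column (other) gives the distance from the peak's start to its summit. The largest q-value was 0.0455 to 0.0500 in the 6 lists. Whether a control library was used, the handling of duplicate reads and the other settings of the peak caller are not given in the sources used here. The fold of a peak is the authors' own value. It was used to describe, rank or filter peaks within a list, to give the largest fold per list, and to recover the pileup and local background of each peak as described below.

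The lists hold no read counts. In MACS2 the fold is (pileup + 1)/(background + 1) and the p-value is a Poisson tail, so each peak's pileup and local background were solved from the deposited fold and −log10 p-value. A whole-number pileup was found, within 0.002 of the −log10 p-value, for 99.96% to 100% of the peaks with a −log10 p-value below 30 in each list. The commonest local background of a list is its genome-wide background pileup and served as a measure of depth. It also depends on the width over which each read is counted, so it is a rough measure between lists. On simulated data the step recovered 100% of 1000 pileups, and the region step recovered 100 of 100 simulated OE-only and 60 of 60 simulated NC-only regions.

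Peaks of all 6 lists overlapping by at least 1 bp were merged into regions. A region is called OE-only when all 3 OE lists and 0 NC lists hold a peak in it, NC-only in the reverse case, and shared when all 6 lists hold one. Gene models came from GENCODE release 29 on GRCh38, the build of the lists. A peak was counted at a promoter when its summit lay within 1 kb of the transcription start site (TSS) of a protein-coding gene, and a gene or region was given a promoter peak or called a promoter region when the peak came within 3 kb of such a TSS. Coordinates are 1-based. Groups were compared with a two-sided exact permutation test over the 20 assignments of the labels, in which 3 against 3 lists cannot give a p below 0.1. Similarity of lists was measured by the Jaccard index of covered bases (shared over total) and tested over the 10 splits of the lists. Members of 15 gene lists were counted per peak list and tested with Fisher's exact test, with Benjamini-Hochberg adjustment over lists and directions. Of 551 listed genes 549 were matched. The lists were STAT3 targets, LIF/IL-6 receptors and JAK-STAT components, immune checkpoint ligands and receptors, antigen presentation, interferon-stimulated genes, cytokines and chemokines, AP-1 and immediate-early genes, epithelial-mesenchymal transition, cell cycle and apoptosis regulators, pancreatic cancer drivers and pathways, ribosomal protein genes, and 4 control lists of hepatocyte, haematopoietic, fibroblast and endothelial, and neuronal genes.

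Genes named in the text followed a rule fixed beforehand. It takes CD274, LIFR, STAT3 and SOCS3, the 10 genes with the highest mean within-list percentile of fold among OE-only and likewise among NC-only promoter regions on chromosomes 1 to 22, X and Y, the 5 highest among shared promoter regions, and up to 4 members of each gene list per direction. Some genes that the rule takes are not reported here. Genes outside the rule are said to have been chosen after their values were seen. The test for the STAT sequence motif needs the genome sequence, which was not used here, so that test was not run. Alternatives were a stricter q-value (0.001), equal list lengths, each replicate left out, other chromosomes, overlap rules, promoter windows and a replicate block. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.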

Results

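Anti-STAT3 CUT&Tag was used to look for genes bound by STAT3 in Mia PaCa2 pancreatic cancer cells, and for sites with more STAT3 when LIFR, the receptor of the cytokine LIF, is over-expressed. The series names PD-L1, the immune checkpoint ligand encoded by CD274, as the gene of interest. There were 3 peak lists of untreated cells (NC) and 3 of LIFR-over-expressing cells (OE). The NC lists held 7372, 8240 and 6983 peaks and the OE lists 6589, 8538 and 9685. As a measure of depth, the genome-wide background pileup was 1.27, 2.03 and 1.79 in the NC lists and 1.499, 2.01 and 2.07 in the OE lists, so NC replicate 1 was the shallowest list.

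The CD274 promoter carried no peak. In 0 of the 6 lists did a peak come within 3 kb of a CD274 TSS (gene at chromosome 9, positions 5450503 to 5470566, plus strand). Upstream of the gene, all 3 NC lists had a peak with its summit 12.5 to 13.1 kb from the TSS, between positions 5437178 and 5438368, with folds of 6.62, 8.25 and 7.52. All 3 OE lists had a peak 11.8 kb upstream, between positions 5438634 and 5438933, with folds of 6.003, 5.32 and 7.497, and no NC peak overlapped it. OE replicate 3 also had a peak 13.2 kb upstream that overlapped the NC peaks. The neighbouring gene PLGRKT (minus strand, positions 5357973 to 5437878), named after the values were seen, begins at position 5437878, inside all 3 NC peaks. The OE peaks 11.8 and 13.2 kb upstream of CD274 lie within 3 kb of that position. By the promoter rule used here these are promoter peaks of PLGRKT, and their position does not assign them to CD274. OE replicates 1 and 3, and 0 of 3 NC lists, had a peak 3.6 kb upstream with folds of 4.002 and 6.19, between positions 5446733 and 5447328. A peak present in 2 of 3 lists against 0 of 3, or in 3 of 3 against 0 of 3, cannot reach p below 0.1 in an exact test of these 6 lists.

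**Figure D1:**
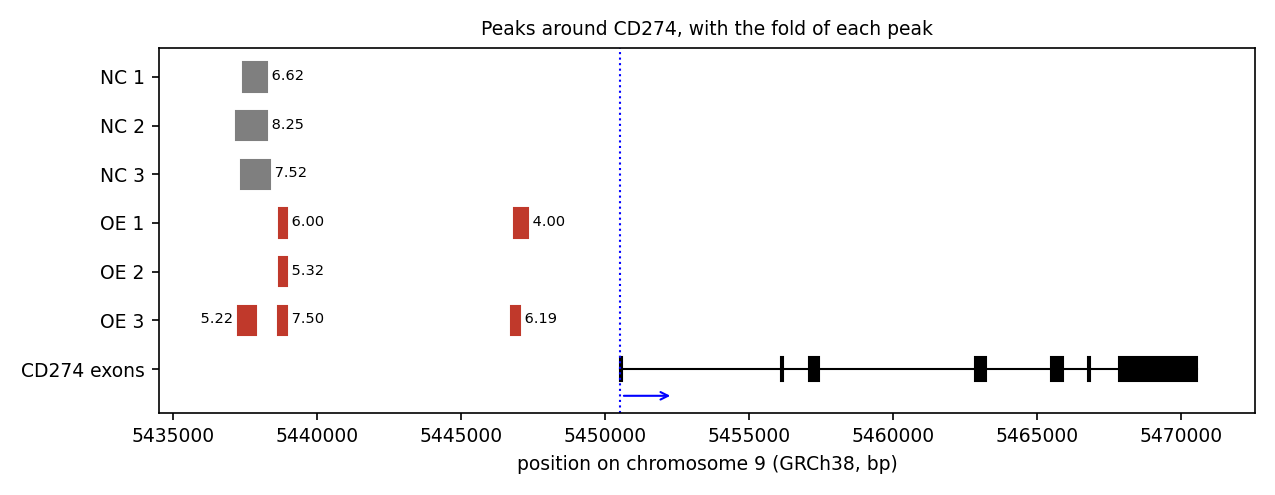
Peaks of the 6 lists (boxes, NC grey and OE red) along chromosome 9 (GRCh38, horizontal axis in bp), with the CD274 exons in black, its TSS as a dotted line and the fold of each peak printed beside it. All peaks lie upstream of the gene: the NC peaks 12.5 to 13.1 kb from the TSS, and the OE peaks at 11.8 kb, 13.2 kb and 3.6 kb. The neighbouring gene PLGRKT (minus strand), which is not drawn, begins at position 5437878, inside the NC peaks.

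STAT3 itself had a promoter peak in all 6 lists (chromosome 17, gene at positions 42313324 to 42388568, minus strand). In the OE lists the summit lay upstream of the TSS, with peaks between positions 42388256 and 42389231, folds of 11.4, 14.9 and 12.5 and pileups of 45, 80 and 77. In NC replicates 1 and 3 the peaks lay inside the gene, from position 42387743 to at most 42388146, with folds of 3.66 and 4.84 and pileups of 15 and 18. NC replicate 2 had a peak from 42387777 to 42388650 whose pileup of 52 stood over a local background of 29.1, for a fold of 1.76. The local background under the OE peaks was 3.05, 4.43 and 5.23. Folds of lists with different backgrounds are not comparable, so these values show position and not a change in binding.

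**Figure D2:**
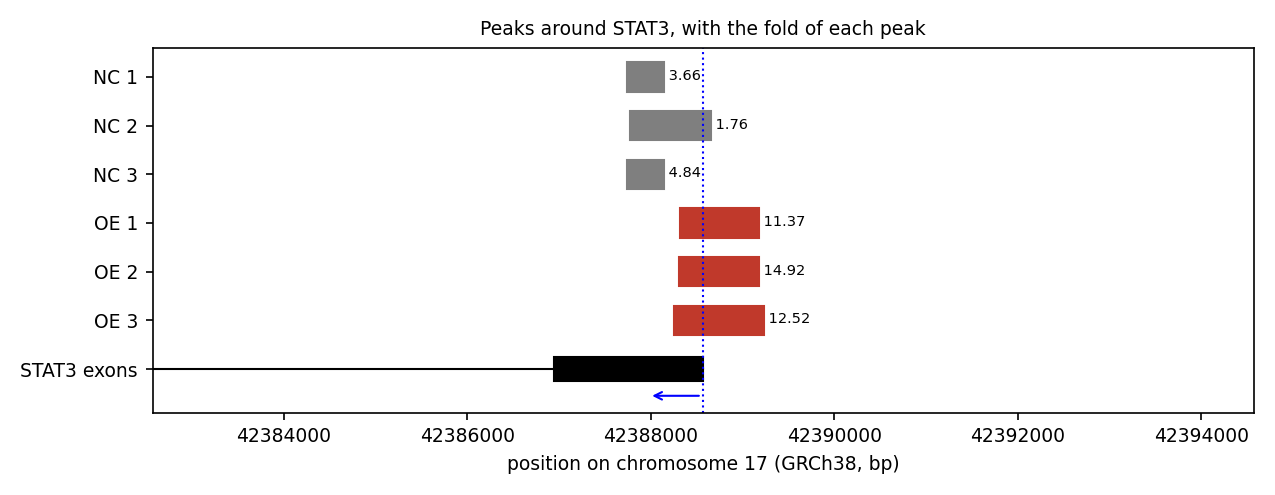
Peaks of the 6 lists (boxes, NC grey and OE red) around the STAT3 TSS (dotted line, transcription to the left) on chromosome 17 (GRCh38, horizontal axis in bp), with exons in black and the fold of each peak beside it. NC replicates 1 and 3 have peaks inside the gene, the OE peaks span the TSS, and the NC replicate 2 peak reaches into both.

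SOCS3, the feedback inhibitor of STAT3 signalling (chromosome 17, positions 78356778 to 78360077), had a promoter peak in 3 of 3 NC lists and in 2 of 3 OE lists. Its summits lay 908, 642 and 895 bp upstream of the nearest TSS in the NC lists and 643 bp upstream in OE replicates 2 and 3, while the nearest peak of OE replicate 1 had its summit 6594 bp downstream of a TSS. LIFR had no promoter peak in any of the 6 lists. Within 50 kb of LIFR (chromosome 5, positions 38474963 to 38608354), NC replicate 1 and OE replicate 2 had 1 peak each, with folds of 3.53 and 5.65.

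The number of peaks was 8271 ± 1565 in OE and 7532 ± 644 in NC (mean ± SD, n = 3 each), a difference smaller than the spread of the lists (exact permutation p = 0.6). Promoters took a larger share of the OE peaks. The share within 1 kb of a TSS was 45.1% ± 1.014 in OE and 37.4% ± 3.74 in NC (SD, n = 3 each), with every OE list above every NC list (exact permutation p = 0.1, the smallest possible). Introns held 25.1% ± 1.08 of the OE peaks and 32.1% ± 2.18 of the NC peaks (SD, n = 3 each, exact permutation p = 0.1). Peak summits shifted by 1 Mb lay at promoters in 7.41% and 6.88% of cases. Genes with a promoter peak numbered 4753 ± 700 in OE and 3755 ± 387 in NC (SD, n = 3 each, exact permutation p = 0.2).

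**Figure D3:**
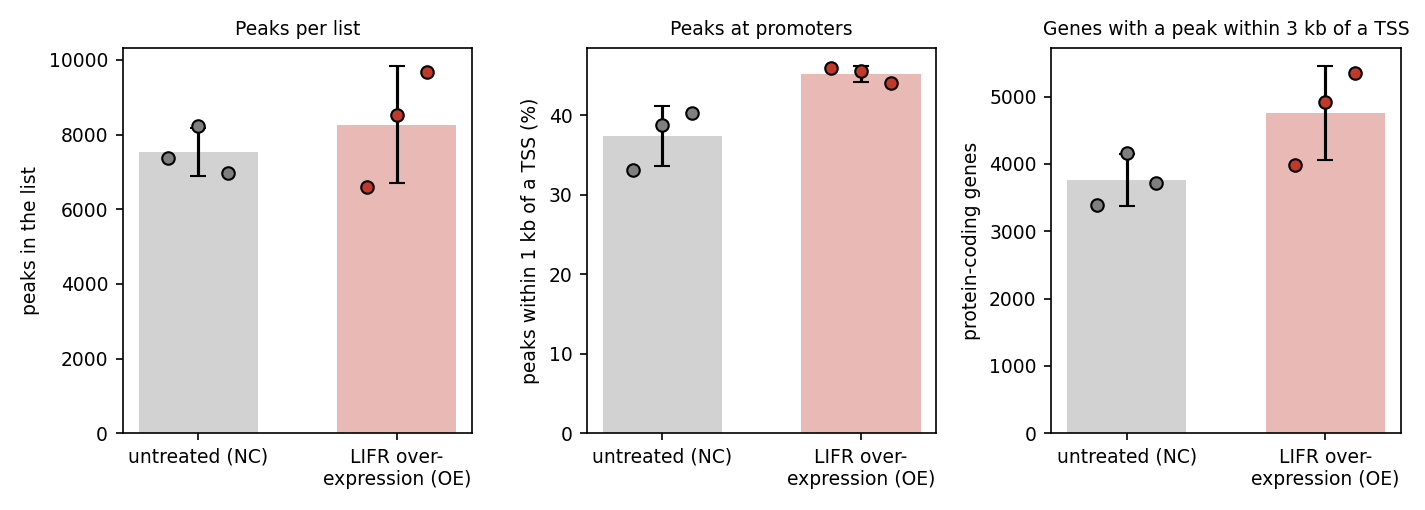
Peaks per list, share of peaks within 1 kb of a TSS (%) and protein-coding genes with a peak within 3 kb of a TSS, for the untreated (NC, grey) and LIFR-over-expressing (OE, red) lists. Points are the 3 lists of a group, bars their mean and error bars the SD: only the promoter share separates all lists of the groups, at 33.1% to 40.2% in NC and 44.0% to 45.9% in OE.

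Lists resembled each other more within a group than between groups. The Jaccard index averaged 0.359 among the OE lists (0.330 to 0.393), 0.239 among the NC lists (0.218 to 0.273) and 0.0974 between the groups (0.0821 to 0.110). The mean within groups exceeded that between groups by 0.202 (exact permutation p = 0.1 over 10 splits, the smallest possible). Merging gave 27637 regions, of which 18416 (66.6%) were seen in 1 list.

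The strongest shared promoter regions lay at C14orf93, RNF31, LGALS3BP, GEN1 and RRM2B. RNF31 is the catalytic subunit of the linear ubiquitin ligase, LGALS3BP a secreted glycoprotein that binds galectin-3, GEN1 a Holliday junction resolvase and RRM2B a subunit of ribonucleotide reductase. LGALS3BP had folds of 37.6, 54.4 and 31.5 in the NC lists and 14.3, 12.8 and 12.5 in the OE lists (chromosome 17, positions 78974035 to 78978583). RNF31 had folds of 14.6, 26.1 and 16.7 in NC and 14.3, 13.7 and 15.7 in OE (chromosome 14, positions 24146443 to 24147618). Folds are not comparable between the groups, whose lists had largest folds of 269 to 302 in NC and 39.1 to 40.6 in OE, so they show no change in binding. The median fold went the other way, averaging 4.55 in NC and 5.45 in OE. In all, 824 regions were in all 6 lists, 517 of them promoter regions.

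Among genes of the fixed lists with a shared region, chosen after their values were seen, were IRF1 and IRF9, transcription factors of the interferon response, and MYC, JUN and MUC1. IRF1 had folds of 23.4, 32.9 and 30.8 in the NC lists and 8.43, 6.35 and 6.59 in the OE lists (chromosome 5, positions 132488950 to 132492382), which again are not comparable between the groups. STAT3 targets were over-represented among genes with a shared region, with 6 of 48 members (12.5%) against 3.56% of all protein-coding genes (odds ratio 3.89, Fisher's exact test, adjusted p = 0.0344 over the 15 lists). They included IRF1, MYC and STAT3. The STAT3 region counts as shared only through the NC replicate 2 peak (fold 1.76), which joins NC and OE peaks that do not overlap each other. The test was not repeated without STAT3. Tests of gene lists among shared regions were not planned beforehand, and no alternative was run for them. Measured against genes with a region in any list, STAT3 targets had an odds ratio of 3.37 and did not pass (Fisher's exact test, adjusted p = 0.123). By the same exact test, ribosomal protein genes passed on both backgrounds, with 10 of 50 members and odds ratios of 6.85 (adjusted p = 0.000131) and 3.82 (adjusted p = 0.0152), and AP-1 and immediate-early genes passed on the first only (6 of 41, odds ratio 4.67, adjusted p = 0.0233, against adjusted p = 0.156). Immune checkpoint genes had a shared region in 0 of 37 members, and hepatocyte, haematopoietic, and fibroblast and endothelial genes in 0 of 30, 0 of 30 and 0 of 27, while the fourth control list, of neuronal genes, had 2 of 30 (6.67%, odds ratio 1.94, Fisher's exact test, adjusted p = 0.622).

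OE-only regions numbered 1895, of which 1202 were promoter regions, and NC-only regions 666, of which 464 were promoter regions. By fold percentile the leading OE-only genes were MRPS31, MTRNR2L7, ECM2, MTRNR2L13, SMG1, MTRNR2L4, SGCE, BRF1, MTRNR2L11 and KAT6B. The MTRNR2L genes are nuclear copies of the mitochondrial 16S ribosomal RNA gene, and the OE-only regions at MTRNR2L11, MTRNR2L7, MTRNR2L13 and MTRNR2L4 had pileups of up to 10420, 7793, 2045 and 1110. The MRPS31, ECM2 and SGCE regions reached pileups of 2576, 533 and 115, against a median pileup of 13 to 16 over all peaks of the OE lists. SMG1, a kinase of nonsense-mediated decay, BRF1, a subunit of the RNA polymerase III factor TFIIIB, and KAT6B, a histone acetyltransferase, had pileups of at most 86, 69 and 75. SMG1 had folds of 21.6, 21.4 and 21.7 in the OE lists (chromosome 16, positions 18926566 to 18927153), BRF1 17.6, 19.6 and 19.7 (chromosome 14, positions 105301038 to 105301815) and KAT6B 17.5, 18.9 and 19.2 (chromosome 10, positions 74826069 to 74826737). BRF1 had another promoter peak in 3 of 3 NC lists.

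The leading NC-only genes were AVL9, YWHAQ, NDUFS8, NOL7, SYNJ1, ZNF594, TDG, STXBP3, MED19 and PRCC. YWHAQ is a 14-3-3 protein, NDUFS8 a subunit of respiratory complex I, TDG a thymine DNA glycosylase and MED19 a subunit of Mediator. AVL9 had folds of 15.6, 14.8 and 17.4 in the NC lists (chromosome 7, positions 32495401 to 32496359), YWHAQ 12.8, 14.5 and 12.2 (chromosome 2, positions 9630793 to 9631541) and NDUFS8 10.1, 18.5 and 15.4 (chromosome 11, positions 68030431 to 68031327). All 10 regions had summits within 300 bp of a TSS and pileups of at most 55, and PRCC and SYNJ1 had another promoter peak in 3 and 1 of 3 OE lists.

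**Figure D4:**
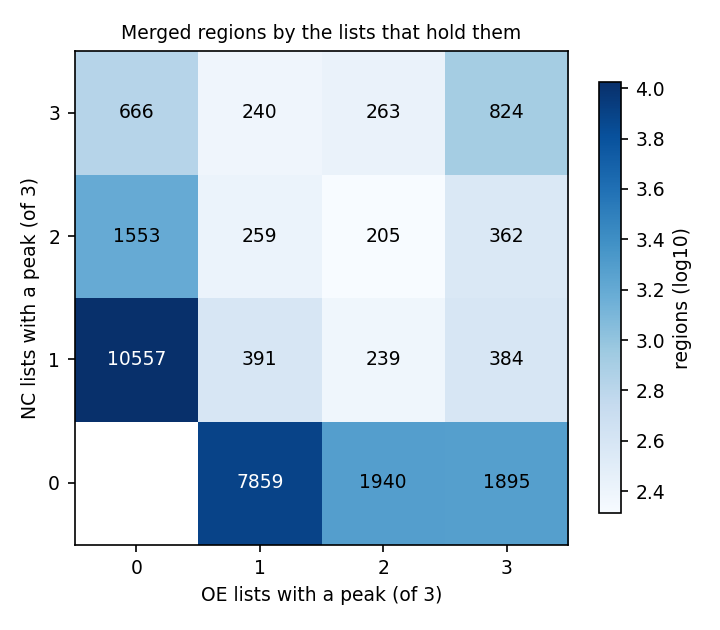
Number of merged regions by how many NC lists (vertical axis, of 3) and OE lists (horizontal axis, of 3) hold a peak, with shading on a log10 scale. The corners show 666 NC-only, 1895 OE-only and 824 shared regions, and most regions (10557 and 7859) are in a single NC or OE list.

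Several measures set the groups apart beside these counts. Regions with a pileup over 100 made up 182 of the 1895 OE-only regions (9.60%) and 4 of the 666 NC-only regions (0.601%). Shared regions had the largest share, 118 of 824 (14.3%). Those at LGALS3BP, RNF31 and IRF1 were among them, with pileups of up to 325, 142 and 102. Another 96 OE-only and 10 NC-only regions, some of them the same, lay outside chromosomes 1 to 22, X and Y, and 54 and 2 lay over nuclear copies of mitochondrial genes. Without all of these, 1630 OE-only (1185 promoter) and 653 NC-only regions (464 promoter) remained, a count chosen after the data were seen. The largest fold was 269, 302 and 273 in the NC lists and 40.6, 39.2 and 39.1 in the OE lists. The median fold was instead higher in OE, at 5.45 ± 0.163 against 4.55 ± 0.125 in NC (SD, n = 3 each, exact permutation p = 0.1). At the 487 shared promoter regions outside these classes, the local background stood above the genome-wide one in 65.0% ± 0.517 of cases in NC and 48.0% ± 1.44 in OE (SD, n = 3 each), and its 90th percentile was 6.38 to 6.93 times the genome-wide background in NC and 1.94 to 2.06 times in OE. The groups and this difference in background cannot be separated with these lists.

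Leaving out a list raised the counts, since 2 lists then sufficed. Without OE replicate 1, the OE-only count was 3048, and without NC replicates 1, 2 and 3 the NC-only count was 1378, 1012 and 1222. Of the genes with an OE-only promoter region, 584 of 1511 also had another promoter peak in an NC list, and of those with an NC-only region 243 of 550 had one in an OE list. Counted by gene, 974 genes had promoter peaks in 3 OE and 0 NC lists, 356 in 3 NC and 0 OE lists, and 940 in all 6 lists.

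STAT3 targets had 7 of 27 members with an OE-only region (25.9%, against 16.7% of genes with a region in any list) and 4 with an NC-only region (14.8%, against 6.08%). Neither passed Fisher's exact test (odds ratios 1.75 and 2.70, adjusted p = 0.816 and 0.678). The OE-only regions lay at the anti-apoptotic gene BCL2L1, the hypoxia factor HIF1A, VMP1 and TNFRSF1A, among others, and VMP1 and TNFRSF1A also had a promoter peak in 2 of 3 NC lists. BCL2L1 had folds of 8.01, 11.0 and 9.15 in the OE lists (chromosome 20, positions 31723641 to 31724052) and HIF1A 8.003, 12.6 and 7.82 (chromosome 14, positions 61695313 to 61696062). At FOSL2 and IRF9, NC-only regions lay beside shared ones. Per list, 20, 22 and 24 of the 48 STAT3 targets had a promoter peak in OE and 15, 20 and 18 in NC (exact permutation p = 0.2).

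LIF/IL-6 receptors and JAK-STAT components had a promoter peak for 12, 16 and 18 of 42 members in OE and 11, 11 and 9 in NC (exact permutation p = 0.1, adjusted p = 0.3). Genes with a promoter peak were more numerous in OE in general (4753 against 3755). OE-only regions were not over-represented in this list, with 3 of 24 members (12.5%, against 16.7% of genes with a region in any list, odds ratio 0.711). An NC-only region was found for 1 of 24 (4.17%, against 6.08%). PIAS3, an inhibitor of STAT3, had an OE-only region with folds of 12.02, 11.96 and 15.1 (chromosome 1, positions 145858998 to 145859699), and the cytokine-signalling suppressor SOCS5 one with folds of 10.4, 8.64 and 5.54 (chromosome 2, positions 46698476 to 46699156). Immune checkpoint ligands and receptors had a promoter peak for 3, 2 and 4 of 37 members in OE and 1, 4 and 1 in NC (exact permutation p = 0.6). CMTM4, a membrane protein that can stabilise PD-L1, was the member with an OE-only region, with folds of 4.002, 3.65 and 3.59 (chromosome 16, positions 66696948 to 66697292). That is 1 of 7 members with a region (14.3%, against 16.7% of genes with a region in any list, odds ratio 0.831). Antigen presentation genes had 5, 5 and 4 of 29 members in OE and 2, 3 and 5 in NC (exact permutation p = 0.4), and the chaperone gene CANX had an OE-only region with folds of 12.4, 8.97 and 12.3 and another promoter peak in 2 of 3 NC lists.

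Interferon-stimulated genes had a promoter peak for 8, 8 and 10 of 46 members in OE and 5, 8 and 7 in NC (exact permutation p = 0.3). IFIT2, which encodes an antiviral RNA-binding protein, had an NC-only region with folds of 5.88, 5.94 and 7.17, and IFITM1, an antiviral membrane protein, one with folds of 5.11, 3.07 and 4.15. ISG20 and IRF3 had OE-only regions, with folds of 4.40 to 5.65 and 4.66 to 5.22, and IRF3 also had a promoter peak in 2 of 3 NC lists. Cytokines and chemokines had 2, 5 and 2 of 40 members with a promoter peak in OE and 2, 4 and 4 in NC (exact permutation p = 1.0).

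AP-1 and immediate-early genes were over-represented among genes with an NC-only region, with 8 of 31 members (25.8%) against 6.08% of genes with a region (odds ratio 5.43, Fisher's exact test, adjusted p = 0.0121). This was the 1 call among 30 tests of lists and directions. The number of members with a promoter peak did not follow it, with 21, 23 and 22 of 41 in OE and 13, 22 and 22 in NC (exact permutation p = 0.7), and by gene 3 members had promoter peaks in 3 NC and 0 OE lists and 3 in 3 OE and 0 NC lists. The 8 were FOSL2, DUSP1, MAFK, EGR3, IER2, KLF2, FOSB and ATF4, and of these DUSP1, EGR3 and KLF2 had no promoter peak in any OE list. DUSP1, MAFK, IER2 and, in this direction, ATF4 were named after their values were seen. EGR3 had folds of 5.88, 6.93 and 5.02 (chromosome 8, positions 22694063 to 22694683). The same list had 7 members with an OE-only region, among them FOS, SRF, ATF2 and ATF4, of which FOS and ATF4 also had promoter peaks in 1 and 3 of 3 NC lists (odds ratio 1.46, Fisher's exact test, adjusted p = 1.0). Across 12 alternatives the NC-only adjusted p ran from 9.08e-05 to 0.844 and 6 passed. Without NC replicate 2, NC replicate 3 or OE replicate 3 the adjusted p was 0.382, 0.256 and 0.0605.

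Ribosomal protein genes had a promoter peak for 26, 28 and 33 of 50 members in OE and 18, 20 and 18 in NC (29 ± 3.61 against 18.7 ± 1.15, SD, n = 3 each, exact permutation p = 0.1, adjusted p = 0.3). They included RPL27, RPS9 and RPS24, each with an OE-only region. Such a region was found for 11 of 41 members with a region (26.8%, against 16.7% of genes with a region in any list). This did not pass (odds ratio 1.83, Fisher's exact test, adjusted p = 0.678). Genes with a promoter peak were also more numerous in OE in general (4753 against 3755). Cell cycle and apoptosis regulators had 19, 23 and 29 of 49 members in OE and 20, 22 and 19 in NC (exact permutation p = 0.5), with OE-only regions at CASP9, CASP8, CDKN2D and BCL2L1 and NC-only regions at BIRC3 and E2F4. CASP9 and CDKN2D also had a shared region, CASP8 a promoter peak in 1 of 3 NC lists and E2F4 one in 2 of 3 OE lists. In this list 10 of 38 members with a region had an OE-only one (26.3%), which did not pass (odds ratio 1.79, Fisher's exact test, adjusted p = 0.678). The NC-only region of BIRC3, an inhibitor of apoptosis, had folds of 6.17, 10.6 and 7.88 (chromosome 11, positions 102317154 to 102317942). Epithelial-mesenchymal transition genes had 12, 14 and 12 of 42 members in OE and 11, 10 and 10 in NC (exact permutation p = 0.1, adjusted p = 0.3), with OE-only regions at VIM, S100A4, ITGB1 and CLDN1. Of these 4, ITGB1 also had a promoter peak in 3 of 3 NC lists and VIM and S100A4 in 1 NC list each. In this list 6 of 22 members with a region had an OE-only one (27.3%), which did not pass (odds ratio 1.87, Fisher's exact test, adjusted p = 0.816). By gene, 2 members had promoter peaks in 3 OE and 0 NC lists and 2 in 3 NC and 0 OE lists, the latter COL1A2 and KRT18, named after their values were seen. Pancreatic cancer drivers had 13, 12 and 13 of 45 in OE and 10, 11 and 11 in NC (exact permutation p = 0.1, adjusted p = 0.3), with OE-only regions at ATM, KMT2A and ARID1A, of which KMT2A and ARID1A also had a promoter peak in 1 NC list each. These are 3 of 19 drivers with a region (15.8%, against 16.7% of genes with a region in any list, odds ratio 0.934).

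Control lists of other cell types had few promoter peaks, as had the immune checkpoint and cytokine lists above. Hepatocyte genes had 1, 3 and 1 of 30 members in OE and 0, 0 and 1 in NC (exact permutation p = 0.3), fibroblast and endothelial genes 2, 3 and 2 of 27 in OE and 2, 4 and 4 in NC (exact permutation p = 0.4), and neuronal genes 5, 4 and 6 of 30 in OE and 5, 3 and 3 in NC (exact permutation p = 0.3). Haematopoietic genes had 3, 2 and 4 of 30 members in OE and 1 in each NC list (exact permutation p = 0.1, adjusted p = 0.3). The haematopoietic gene HBB, which encodes beta-globin, had an OE-only region with folds of 13.4, 11.9 and 12.4 and a pileup of up to 67 (chromosome 11, positions 5224960 to 5226658). Its summit lay in an exon, 1585 bp downstream of the TSS, and so not within 1 kb of it.

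**Figure D5:**
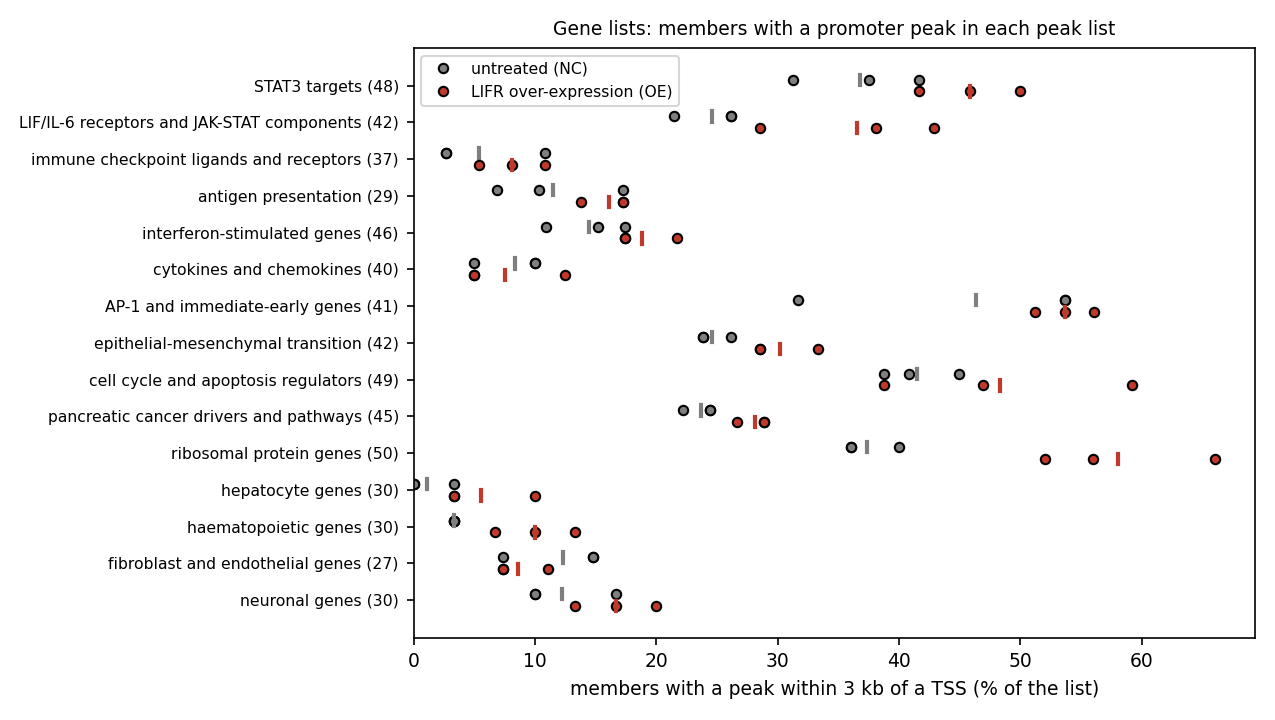
Share of each gene list's members with a peak within 3 kb of a TSS (horizontal axis, % of the members given in parentheses), for each NC list (grey points) and OE list (red points), with the mean of each group as a bar. Ribosomal protein genes show the widest gap in members, 29 against 18.7 of 50. The control lists lie low in both groups, but so do the immune checkpoint and cytokine lists, whose means lie below those of the neuronal control list.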

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

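All alternatives were fixed before the data were examined, except the removal of unplaced, mitochondrial-copy and high-pileup regions (OE-only 1630, NC-only 653) and the rule that no peak of the other group lies within 2 kb (1543 and 478). Both kept more OE-only than NC-only regions, and so did every other alternative run. Counting regions in 2 or 3 of 3 lists against 0 gave 6054 regions, 3835 OE-only and 2219 NC-only, because the criterion is looser. Leaving out each list in turn gave 3082 to 3747 regions, 1978 to 3048 OE-only and 699 to 1378 NC-only. It gave peak differences (OE minus NC) of 31.8 to 1580, promoter-share differences of 5.64 to 9.18 points, 696 to 1382 more genes with a promoter peak in OE, and overlap differences of 0.166 to 0.235. The promoter share stayed higher in OE under every alternative run, though the replicate block keeps its difference by construction. The number of gene lists past the threshold was 1, but 0 with q below 0.001, 0 with equal list lengths and 0 with promoters within 1 kb, and 0 to 2 on leaving out each list. The cause was not tested. The count of 0 lists with a promoter peak at CD274 was not put to a test, since its alternatives run here only remove peaks or narrow the window and so keep 0 by construction.

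Gene-list differences kept their direction in 169 of 180 alternatives. That count includes the replicate block, which keeps every difference by construction. It also includes the restriction to fewer chromosomes, which left the difference of every list unchanged. Neither puts the direction to a test, so the count overstates how far it was tested. The neuronal list turned to −0.333 members with q below 0.001 and −1.0 with gene body and 10 kb, and the hepatocyte list to −0.333 with promoters within 1 kb. Cytokines and chemokines ranged from −1.33 to 0.167 on leaving out each list.

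Same-numbered NC and OE lists did not deviate together (correlations −0.0044, −0.0034 and 0.0064 over regions). The lists thus show no sign of pairing by number, but this cannot settle whether same-numbered samples were prepared together. With a replicate block (smallest possible p 0.25), peaks differed by 739 (p = 0.75), the promoter share by 7.76 points (p = 0.25) and genes with a promoter peak by 998 (p = 0.25, exact sign-flip permutation, n = 3 pairs). The differences are the same as without the block by construction. No call could change, since neither test can give a p below 0.05 here. All alternatives of the STAT motif test were not run, since no genome sequence was used here. Peak number under equal list lengths has no value by construction. Without read counts, a region missing from a list shows only that no peak passed there.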

Other observations

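The tests of gene families, of chromosomes, of the largest fold, of mitochondrial pileup, of other splits and of interferon-stimulated genes were chosen only after the result was seen. Those of depth, of shifted peaks, of raised local background and of the NC-only peaks were chosen before.

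Histone genes stood out among 8 gene-name families tested in 3 directions. OE-only regions touched the promoters of 23 of 60 histone genes with a region (38.3%, against 16.7% of all genes with a region, odds ratio 3.13, Fisher's exact test, adjusted p = 0.000782), and shared regions those of 16 of 60 (26.7% against 7.86%, odds ratio 4.34, adjusted p = 0.000243). Histone genes lie in clusters, so the 23 genes came from 13 regions and are not independent. HIST1H4B, HIST1H3B and HIST1H2AB on chromosome 6 and HIST3H2A and HIST3H2BB on chromosome 1, named after their values were seen, had promoter peaks in 3 of 3 OE and 0 of 3 NC lists. Transmembrane protein genes of the TMEM family had an OE-only region in 32 of 119 members (26.9%, odds ratio 1.85, Fisher's exact test, adjusted p = 0.0343), and zinc finger (ZNF) genes in 43 of 258 (16.7%, adjusted p = 1.0).

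Chromosome 19 held 200 OE-only regions out of 1825 regions in any list (11.0%, against 6.32% on the other chromosomes, odds ratio 1.82, Fisher's exact test, adjusted p = 4.93e-11 over chromosomes and directions). It held 7.82% ± 0.0877 of all peaks in OE and 6.39% ± 0.551 in NC (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Fisher's test here counts merged regions of the same 6 lists as independent units. Its p-value does not measure the spread between lists. With regions of very high pileup set aside, a step chosen after the values were seen, the leading OE-only promoter regions were SMG1, BRF1, KAT6B, ELL, KDM4A, HDGFL2, GSTZ1, FXR2, IMPA2 and FBXL12, of which ELL, a polymerase II elongation factor, HDGFL2 and FBXL12 lie on chromosome 19. ELL had folds of 17.4, 18.2 and 18.6 in the OE lists (positions 18522174 to 18522617). ELL, HDGFL2 and FBXL12 also had another promoter peak in 3, 2 and 2 of 3 NC lists.

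The first pattern is the OE-only regions of very high pileup. More mitochondrial DNA in the OE libraries was not decided. The mitochondrial pileup over background was 1.28 times higher in OE (exact permutation p = 0.1, the smallest possible), and 1.34 times from the highest OE to the lowest NC list. That is far below the 10 times named for this explanation, but the bound was set after the values were seen and so could not fail. Peak calling without a control library in OE remains open and could account for these OE-only regions. The largest OE fold was 0.995, 0.996 and 0.998 of the ceiling set when the background is the list's own mean over an assumed 10 kb. In NC the largest fold was 7.61 to 8.41 times that ceiling, and 3 peaks in each NC list lay above it. The labels name input samples for NC alone. This is a hypothesis, since the settings of the caller are not given in the sources used here.

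The second pattern is the excess of OE-only over NC-only regions. It was not particular to promoters, since promoter regions made up 63.4% of the OE-only and 69.7% of the NC-only regions. Greater depth of the OE lists was not decided. With NC replicates 2 and 3 (background 1.91) against OE replicates 1 and 2 (1.75) the ratio was 1.52 (95% interval 1.43 to 1.62, counting error only). That is above the 1 named for depth alone and above the 1.5 set beforehand, but the interval includes 1.5. By background pileup the NC lists were the deeper ones in 2 of the 9 pairings of 2 lists each, with ratios of 1.52 and 1.58. Background pileup also rises with the width over which each read is counted. The smallest peak width was 278 and 279 bp in NC replicates 2 and 3, against 245 and 254 bp in OE replicates 1 and 2. The NC lists may therefore not have held more reads in these pairings. In the other pairings the OE lists had the higher background and the ratio ran from 1.78 to 3.14, so depth may add to the excess. Peaks of the groups shifted within one promoter are argued against as the whole cause, since 21.2% (exact 95% interval 18.9% to 23.6%) of OE-only promoter regions had an NC peak within 2 kb, against 11.3% after a shift of 20 kb. That is far from the majority named for this explanation, but it misses the bound of fewer than 20% set beforehand, so shifted peaks may account for part of these regions. A control library used in NC and not in OE cannot be told apart from LIFR over-expression, because it goes with the groups: the share of shared promoter regions with a raised local background was 16.9 percentage points higher in NC. The effect of LIFR on STAT3 binding stays open as a biological explanation and was not tested separately.

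The third pattern is the NC-only regions. If absence from the OE lists came from calling without a control, the NC peaks should fail when their own mean pileup over 10 kb is the background, and 8.86%, 7.66% and 6.76% of them did in NC replicates 1, 2 and 3. That is far from the majority named for this explanation, but the window and the profile of each peak were assumed and the interval of NC replicate 1 (6.81% to 11.3%) includes the 10% set beforehand, so it stays open. A difference in STAT3 binding between the groups may underlie regions such as AVL9 and is a hypothesis.

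Of the 10 splits of the lists, 1, the real one, gave as many regions in 3 lists of one side and 0 of the other (2561, highest other 78). With 10 splits no share under 0.05 is possible.

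Since IRF1 and IRF9 had shared regions, it was tested whether interferon-stimulated genes as a list were over-represented there. These 2 of 46 members were the only ones with a shared region (odds ratio 1.23, Fisher's exact test, adjusted p = 0.784), so the test holds nothing beyond the observation that prompted it and decides nothing.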
